A study of Mus musculus with 17 samples.

How the data were processed

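The series held chromatin immunoprecipitation libraries (ChIP-seq) of mouse bone marrow cells of a mixed C57BL6/Sv129 strain, depleted of mature lineages with antibodies against Gr-1, CD11b, B220, CD3e and Ter-119. It listed 17 samples. 15 of them were libraries of 3 histone marks, H3K4me3, H3K27me3 and H2AK119Ub, from 5 animals, and the other 2 were input libraries, which were not analysed here. The animals were labelled WT without disease, TP53 KO with thymic lymphoma, BAP1 KO with myelodysplasia, Double KO with AML (replicate 1) and Double KO with AEL (replicate 2). Per the labels, the libraries of the Double KO AML animal were set against input 2 and all others against input 1. Sex, age and the deleted parts of both genes are not given in the sources used here.

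Reads were aligned with Bowtie2 2.3.4 and islands were called with SICER 1 on GRCm38 (mm10), per the submitters' processing notes. The island threshold, duplicate handling and total sequencing depth are not given in the sources used here. Each deposited file listed the islands of 1 library with a chromosome, a start, an end and a whole number without a column name, which was used as the island's read count because SICER writes counts in that place; the files themselves do not say so. These deposited counts were raw whole numbers and were not scaled to library size. All starts and widths were multiples of 200 bp, and the smallest gap between islands was 400 bp for H3K4me3 and 800 bp for the other marks. Starts count from 0 in such files, so 1 was added to starts and ends to give coordinates counted from 1. Islands had been called for each library separately, so replicates were not pooled and no common set of regions existed for a count model.

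Islands were compared by overlap. Genes came from a RefSeq table of the same build, GRCm38, with 21883 protein-coding genes on 21 main chromosomes. That table gives neither strand nor transcript starts. The plan had been to use the gene start on its strand. Instead, a gene was called marked when an island overlapped by at least 1 bp a window of 1 kb to each side of either gene end. A marked gene therefore may carry the island at its 3' end. Between 12.8% and 38.8% of H3K4me3-marked genes, depending on the library, had islands at both ends. "Covered" lengths given for single genes are island bp between 1 kb before and 1 kb after the gene.

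The log2 ratio of marked genes compares each knockout library with the WT library of the same mark. For Double KO it is the mean of both libraries with their SD (n = 2). All other groups had 1 library per mark, so these differences have no replicate check and no p-value was computed. An exact permutation test of 3 against 2 animals cannot give a two-sided p below 0.1. A gene had the BAP1 pattern when BAP1 KO and both Double KO libraries differed together from WT and TP53 KO, the TP53 pattern when TP53 KO and both Double KO libraries differed from WT and BAP1 KO, and the Double KO pattern when both Double KO libraries differed from the other 3. Gained means island present in the named knockout animals only, and lost means absent from them only. Each count was set beside the 10 ways of choosing as many of the 5 animals. Overlap of marks in bp was set beside 100 circular shifts of the islands along each chromosome. For 14 gene lists (HOX genes, developmental transcription factors, Polycomb and BAP1 complex genes, p53 targets, erythroid, granulocyte and monocyte, T lineage, B lineage, stem and progenitor, megakaryocyte, mast cell and basophil, stromal and endothelial, ribosomal protein, and leukemia and lymphoma genes), the number of marked members was ranked among 10000 random lists of the same size with the same number of WT-marked genes, which describes these libraries and not the genotypes. Ahsp and Tpsab1 were not found among protein-coding genes.

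Designs, lists and the rule for named genes were fixed before the data were examined. The rule named Bap1 and Trp53. It also named up to 10 list members per mark whose state differed from WT, and up to 10 genes per direction of the BAP1 pattern and 5 of the other patterns. Order was by the difference in covered bp within 10 kb of a gene end, leaving out predicted genes and olfactory and vomeronasal receptors. The larger difference of both gene ends was taken because the start was unknown. Of 1480 receptor genes, between 2 and 6 had H3K4me3, between 39 and 111 H3K27me3 and between 2 and 27 H2AK119Ub, depending on the library.

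Alternatives fixed beforehand were a 2 kb window, coverage of at least 50% of a window, the upper 50% of islands by read count, the islands with the most reads up to the covered length of the smallest library of the mark (equal covered length), unmatched random lists, leaving out the sex chromosomes (log2 ratios and co-occurrence), and leaving out either Double KO replicate. Added later were equal covered length by reads per kb, the gene span, 10 kb bins, the gene end with H3K4me3 in more animals, co-occurrence without WT, pattern counts, gains and losses and the AML and AEL comparison without the sex chromosomes, and X shares at equal covered length. The planned use of any transcript start could not be run. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. On simulated islands at real genes, all 200 genes simulated with the BAP1 pattern were recovered with 0 other calls among 21883 genes. These islands always lay in the gene-end window, away from other gene ends, without missed islands or depth differences. Recovery therefore checks the overlap code only and gives no error rate for the real libraries. Covered lengths matched a base-by-base count in 1000 of 1000 intervals, and 4% of lists drawn at random fell outside the central 95% of the percentiles.

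Reads in islands ranged from 1395611 to 15026763 per library. Differences in total depth and in the share of reads inside islands cannot be separated, because reads outside islands were not used here. Wilson 95% intervals are given for shares of island reads and cover counting error only.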

Results

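The data describe 3 histone marks in lineage-depleted bone marrow of 5 mice that carried or lacked Bap1 and Tp53. H3K4me3 marks active and poised promoters, H3K27me3 is laid down by Polycomb repressive complex 2, and H2AK119Ub is laid down by Polycomb repressive complex 1 and removed by the BAP1 deubiquitinase. There was 1 WT, 1 TP53 KO, 1 BAP1 KO and 2 Double KO animals, the latter with AML (acute myeloid leukemia) and AEL (acute erythroid leukemia). In the order WT, TP53 KO, BAP1 KO, Double KO AML and Double KO AEL, islands held 3327764, 15026763, 11384192, 8495086 and 11289041 H3K4me3 reads. They held 2556953, 12072094, 7057990, 2545589 and 9184174 H3K27me3 reads, and 1395611, 5566796, 4345795, 6765994 and 9224491 H2AK119Ub reads. The number of islands ran from 14363 to 24562 for H3K4me3, from 7828 to 25750 for H3K27me3 and from 11586 to 27285 for H2AK119Ub. They covered 63.2, 166, 115, 37.8 and 138 Mb of the genome for H3K4me3, 118, 257, 181, 69.7 and 189 Mb for H3K27me3, and 88.5, 197, 192, 174 and 316 Mb for H2AK119Ub, in the same order. WT had the fewest island reads for H3K4me3 and H2AK119Ub.

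Both targeted genes kept H3K4me3 in all 5 animals. At Bap1 (chromosome 14, 31251352 to 31259930, GRCm38), H3K4me3 islands covered 4.45 kb in WT, 9.05 kb in TP53 KO, 4.85 kb in BAP1 KO, 2.45 kb in Double KO AML and 7.98 kb in Double KO AEL. H2AK119Ub was present at Bap1 only in the 3 animals labelled as lacking it, over 0.13 kb in BAP1 KO, 1.85 kb in Double KO AML and 4.58 kb in Double KO AEL. At Trp53 (chromosome 11, 69580348 to 69591873), H3K4me3 covered between 4.05 kb in Double KO AML and 11.5 kb in BAP1 KO. H2AK119Ub reached Trp53 in WT, BAP1 KO and Double KO AML, and neither gene had H3K27me3. The deleted parts are unknown, so these islands check nothing about the genotype labels.

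The broadest question was how many genes carried each mark in each genotype. H3K4me3 was found at 11851 genes in WT, 13602 in TP53 KO, 13224 in BAP1 KO, 12416 in Double KO AML and 13190 in Double KO AEL. H3K27me3 was found at 5871, 7919, 7254, 4635 and 7705 genes, and H2AK119Ub at 6650, 9883, 9604, 13257 and 11860 genes, in the same order. The log2 ratio to WT for H2AK119Ub was 0.57 in TP53 KO, 0.53 in BAP1 KO and 0.92 ± 0.11 (SD, n = 2) in Double KO. For H3K4me3 it was 0.20, 0.16 and 0.11 ± 0.06, and for H3K27me3 0.43, 0.31 and 0.03 ± 0.52, with the Double KO values at -0.34 in AML and 0.39 in AEL. Nearly all H3K4me3 genes of WT kept the mark, 99.8% in TP53 KO, 99.9% in BAP1 KO and 95.4% in both Double KO animals together. H3K27me3 was kept at 98.2%, 96.7% and 70.0% of the WT genes, the last from 70.6% in AML and 95.9% in AEL alone, and H2AK119Ub at 93.5%, 93.0% and 93.3%. At equal covered length the log2 ratios were negative in TP53 KO, BAP1 KO and Double KO AEL for all 3 marks (for H2AK119Ub -0.53, -0.56 and -0.94), but in Double KO AML they were 0.81 for H3K4me3, 0.25 for H3K27me3 and -0.28 for H2AK119Ub. That setting keeps all islands of the library with the least covered length and as few as 5.10% of another's, so it does not settle which differences belong to the genotypes; ranked by reads per kb, H2AK119Ub stood at 0.71 in AML and -0.51 in AEL.

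**Figure D1:**
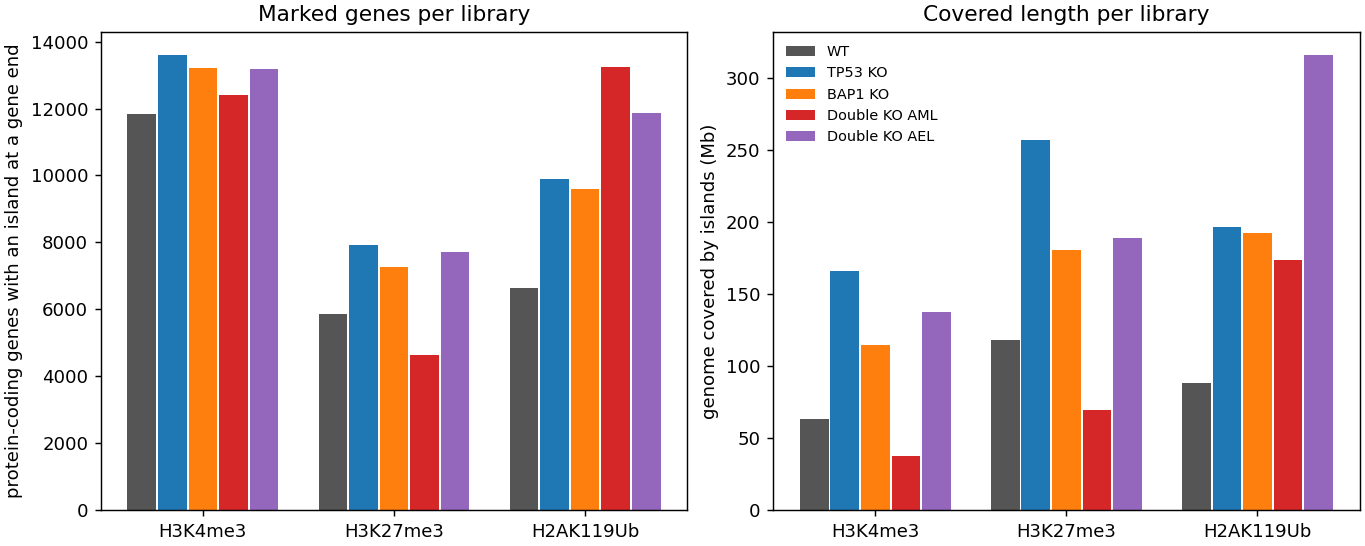
Bars show, for each of the 15 libraries, the number of protein-coding genes with an island at a gene end (left) and the genome length covered by islands in Mb (right), grouped by mark and coloured by animal. H2AK119Ub was found at 13257 genes in Double KO AML and 6650 in WT, while the Double KO AML library had the shortest covered length for H3K4me3 (37.8 Mb) and H3K27me3 (69.7 Mb).

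The mark that BAP1 removes was compared between animals with and without Bap1. H2AK119Ub was present at 562 genes in BAP1 KO and both Double KO animals and in neither WT nor TP53 KO, and 13 genes had the reverse. Of these 562 genes, 87.5% carried H3K4me3 in WT and 10.8% carried H3K27me3 in WT, against 54.2% and 26.8% of all genes. Genes with H2AK119Ub in all 5 animals carried them in 79.3% and 51.4%, and TP53 pattern gains in 71.3% and 27.4%, so frequent H3K4me3 was a feature of H2AK119Ub genes in general. The widest differences were at Mroh2a and its overlapping neighbour Hjurp, a chaperone of centromeric histone H3 (chromosome 1, 88226991 to 88277644). H2AK119Ub covered 37.3, 36.9 and 37.3 kb of Mroh2a in BAP1 KO, Double KO AML and Double KO AEL and none of it in WT or TP53 KO. The strain was mixed and the inputs were not analysed. Whether the animals differed in DNA sequence or copy number at this locus was therefore not checked. Entpd4 and its near-identical copy Entpd4b followed, with 25.8, 20.2 and 30.8 kb at Entpd4, which is uncertain because reads of both copies can be exchanged. Adjacent Med22 and Rpl7a, a Mediator subunit and a ribosomal protein, had 6.58, 7.38 and 7.38 kb and 4.63, 4.63 and 3.23 kb. Cpsf1, Creb3l3, Kifc3 and the pro-apoptotic gene Bid completed the named genes. Away from the gene ends, TP53 KO had 3.2 kb at Creb3l3, 30.4 kb at Kifc3 (WT 4.4 kb) and 14.2 kb at Bid.

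Ribosomal protein genes had H2AK119Ub at 16 of 38 members in WT, 17 in TP53 KO, 25 in BAP1 KO, 33 in Double KO AML and 25 in Double KO AEL, and all 38 had H3K4me3 in every animal. The BAP1 KO count was at percentile 98.6 of random lists, which were not matched on H3K4me3, and at 3.03 at equal covered length. The AML count stood at percentile 99.9 and the AEL count at 76.4, the latter inside the random range. Rpl32, Rps2, Rps19 and Rpl37 followed the BAP1 pattern, with 5.23, 3.14 and 5.23 kb at Rpl32 and 4.6, 5.81 and 5.81 kb at Rps2. Among p53 targets, Ppm1d, the phosphatase that restrains p53, had 3.15, 2.35 and 20.1 kb and Xpc, a DNA repair gene, followed the same pattern at its ends, with 5.4 kb inside the gene in WT. Other list members with it were Phc3, a Polycomb repressive complex 1 subunit, the progenitor antigen gene Cd34, the platelet tubulin gene Tubb1 and, at their ends only, the B cell gene Cd22 and Etv6. Over Etv6 as a whole H2AK119Ub covered 11.6 kb in WT and 23.6 kb in TP53 KO, against 41.1, 4.7 and 11.1 kb in BAP1 KO, AML and AEL. The 562 genes were the largest of the 10 groups of 3 animals, but the group of TP53 KO and both Double KO animals held 551, with 703 against 747 for the BAP1 group without Double KO AML and 904 against 704 without Double KO AEL. With covered length made equal, 58 genes followed the BAP1 pattern as gains and 243 as losses, with the upper 50% of islands 23 as losses, and without Double KO AML or AEL the losses numbered 55 or 44.

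The X chromosome held a lower share of H3K27me3 and H2AK119Ub island reads in every animal without Bap1. The X chromosome held 16.05% of H3K27me3 island reads in WT (95% interval 16.003 to 16.093) and 19.1% in TP53 KO (19.047 to 19.091). It held 11.1% in BAP1 KO (11.104 to 11.150), 3.44% in Double KO AML (3.4208 to 3.4656) and 5.94% in Double KO AEL (5.9241 to 5.9547). The length with H3K27me3 on X was 27.9, 63.1, 29.7, 3.94 and 16.5 Mb, in the same order. For H2AK119Ub the X share was 2.91% (2.8791 to 2.9348) in WT, 3.46% (3.4497 to 3.4801) in TP53 KO, 1.60% (1.5842 to 1.6078) in BAP1 KO, 1.56% (1.5508 to 1.5695) in Double KO AML and 1.15% (1.1401 to 1.1539) in Double KO AEL. The H2AK119Ub length on X was not lower than in WT, with 2.72 Mb in WT, 7.32 Mb in TP53 KO and 3.32, 3.08 and 3.95 Mb in the animals without Bap1. H3K4me3 did not follow, with X shares from 1.49% to 1.66%. Relative to WT, the H3K27me3 share of X was 0.693 in BAP1 KO, where the lowest of the 19 autosomes stood at 0.957, 0.215 in Double KO AML against 0.980, and 0.370 in Double KO AEL against 0.976. This comparison was chosen after its values were seen. With islands ranked by reads per kb at equal covered length, the H3K27me3 separation did not hold: TP53 KO (1.54%) was near BAP1 KO (1.42%) and below Double KO AML (3.44%). For H2AK119Ub it held, with 2.91% in WT and 2.21% in TP53 KO against 0.939%, 1.34% and 0.494%. That ranking kept all WT islands of H2AK119Ub and 16.1% of those of AEL, so it decides nothing for this mark.

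**Figure D2:**
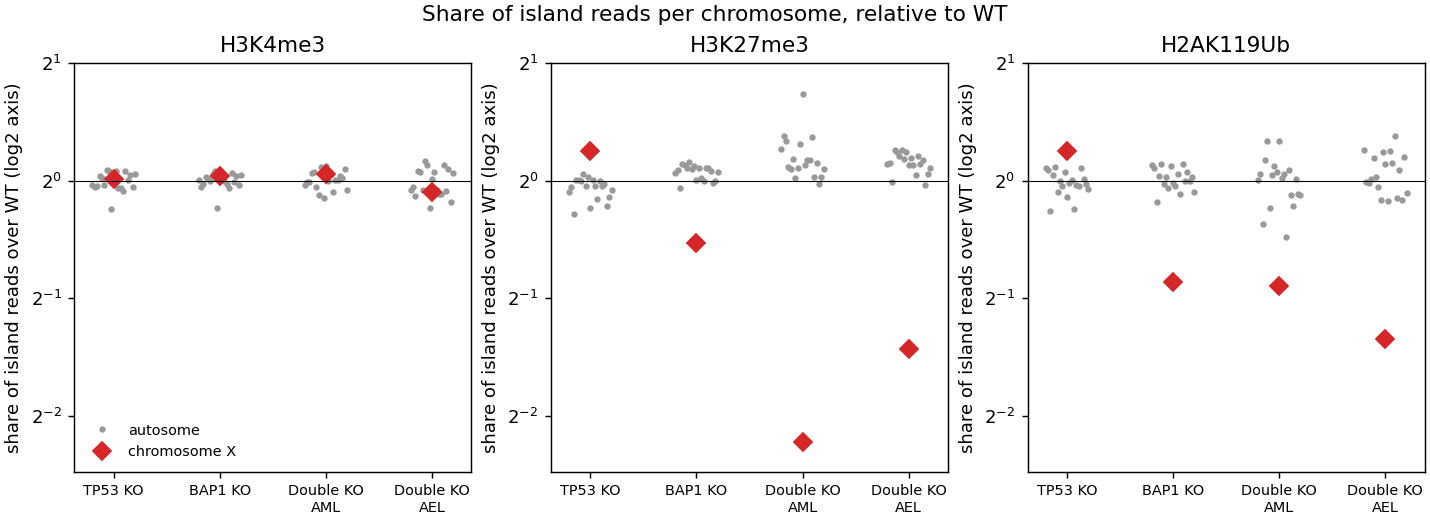
Each grey point is an autosome and each red diamond the X chromosome, plotted as its share of island reads in a knockout library divided by its share in WT, on a log2 axis, for each mark. For H3K27me3 the X chromosome stood at 1.19 in TP53 KO and at 0.693, 0.215 and 0.370 in BAP1 KO, Double KO AML and Double KO AEL, and for H3K4me3 it stayed among the autosomes.

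The genes that lost H3K27me3 together with Bap1 were often X-linked. 73 genes had H3K27me3 in WT and TP53 KO and in no animal without Bap1, and 30 of them (41.1%) were X-linked, against 7.73% of the 5768 genes with H3K27me3 in WT and TP53 KO. All 10 named genes lay on X. Pcyt1b had 50.5 kb covered in WT and 90.3 kb in TP53 KO, against 62.0, 0 and 27.8 kb in BAP1 KO, Double KO AML and Double KO AEL, the islands of the latter avoiding its ends. Gab3 had 12.7 and 88.2 kb against 4.6, 0 and 0 kb, and Rpl39 had 4.62 and 4.71 kb against none. Trex2, Otud6a, Rap2c, Cldn34d, Zfp92, Tbx22 and Cldn34b4 were the others, the last 5 at their ends only, with 6.8 kb left in BAP1 KO at Zfp92 against 5.98 kb in WT. Outside X, Cebpd, a myeloid transcription factor gene, had 2.92 and 2.71 kb against none, and the T cell kinase gene Zap70 was also lost at its ends. Of 13 genes that lost H2AK119Ub in this pattern, 6 were X-linked. Xlr4a, Dmrtc1a and Pola1 of X and the autosomal S100a7a and Fcor had none left without Bap1. Dgat2l6, Igbp1 and Awat2 of X and the autosomal Iqgap1 and Tmem150c lost it at their ends only, Awat2 having 11.7 kb in WT and 20.8 kb in AEL. 39 genes gained H3K27me3 in the BAP1 pattern, including Entpd4, Tbc1d19, Asb13, Serf1, Ankrd28, Ptpn4 (3.0 kb inside the gene in WT), Efl1, Alg8, Bdp1, Crnkl1 and the p53 target Ei24, with 2.41, 2.61 and 6.61 kb at Asb13. Entpd4 is uncertain here too, because of its near-identical copy Entpd4b. The 73 losses ranked 4 of 10 among groups of animals, and the loss count was 43 at equal covered length, 117 without Double KO AEL, and the gains 225 without Double KO AML.

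H3K4me3 differed at few genes together with Bap1. 27 genes had it in BAP1 KO and both Double KO animals alone, and 5 had the reverse. Named gains were the opioid precursor gene Penk (1.2, 1.2 and 2.42 kb), Dmrt1 of the testis, the eye gene Vax2, the lysyl oxidase gene Lox, Nsg1, Degs2, C2cd4b, Clic6 and Gpc6, and, at its ends only, Arhgef7 (10.6, 4.0 and 11 kb against 4.2 kb in WT). The stem cell list contributed Tcf15. The losses were Pou2af1, a B cell transcriptional coactivator gene (1.2 kb in WT, 6.0 kb in TP53 KO), Rassf10, and Trim12a, Trim30d and Trim5 of chromosome 7, which are close paralogs and therefore uncertain. 27 and 5 ranked 4 and 7 of 10, and the gains were 2 with the upper 50% of islands and 15 with 50% of a window required, which gave 9 losses. No loss was left at equal covered length. Without Double KO AML the gains were 60, and without Double KO AEL gains were 50 and losses 9.

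For Tp53, the question was which genes were marked in TP53 KO and both Double KO animals. H3K4me3 was gained at 37 genes and lost at 2, H3K27me3 gained at 31 and lost at 6, and H2AK119Ub gained at 551 and lost at 4. H3K4me3 gains included Mdk, the growth factor midkine gene (4.09, 1.6 and 4.09 kb in TP53 KO, Double KO AML and Double KO AEL, none elsewhere), Syt8 and Rtbdn, and at their ends only Adam33 and Dgkz, a neighbour of Mdk with 16.2 kb in WT and 11 kb in AML. Losses were Tmem100 and, at its ends only, Eps8l1, and Tmem100 also lost H2AK119Ub (8.16 kb in WT, 3.6 kb in BAP1 KO). H2AK119Ub gains included Cd300lg (11.4, 16.1 and 12.6 kb), Kcng4, Adad2, Sertad1 and Gpaa1, and, among list genes, the T cell genes Ptcra, Bcl11b and Tox, the deubiquitinase gene Usp16, Npm1, Aqp1 and Trp53inp1. H2AK119Ub was lost at Ttc8 and Rabif as well, and at the ends of Bclaf1, which kept 2.6 kb in AML. H3K27me3 gains included Ifna4, Rfx3, Cmtm2a, Nme8, Prxl2a, Cd3d and Tek, and losses included Plau, Ifitm1, Man2b2 and Elobl. Cdkn1a, the p53-induced cell cycle inhibitor gene, had H3K4me3 over 2.8 kb in WT, 11.2 kb in TP53 KO, 5.6 kb in BAP1 KO, 2.6 kb in Double KO AML and 7.6 kb in Double KO AEL. It did not follow the TP53 pattern. These lengths ranked the animals as the genome length covered by their H3K4me3 islands did. With covered length made equal, gains and losses in the TP53 pattern were 102 and 25 for H3K4me3, 6 and 24 for H3K27me3, and 48 and 173 for H2AK119Ub. With the upper 50% of islands, H3K4me3 had 5 gains and 0 losses, H3K27me3 13 gains and H2AK119Ub 8 losses, and a 50% window gave 12 and 9 losses for the latter marks. Without Double KO AML or AEL the H3K4me3 gains were 202 or 105, the H3K27me3 gains 369 or 60 and losses 11 or 34, and the H2AK119Ub losses 24 or 35. H3K4me3 losses were 8 and H2AK119Ub gains 904 without Double KO AEL.

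T and B lineage genes were examined next, TP53 KO being the animal with thymic lymphoma. Of 34 T lineage genes, 25 had H3K4me3 in TP53 KO, against 11 in WT, 17 in BAP1 KO, 12 in Double KO AML and 16 in Double KO AEL, a count at percentile 100 of random lists. The same list had H2AK119Ub at 22 genes in TP53 KO against 12 in WT (percentile 99.2) and H3K27me3 at 20 against 15 (percentile 94.5). H2AK119Ub was at 18 in BAP1 KO, 22 in AML and 25 in AEL (AEL percentile 98.8). H3K27me3 was at 18, 10 and 20 (AEL percentile 96.2), so neither count was particular to TP53 KO. Rag1, a recombinase gene of lymphocyte precursors, had H3K4me3 over 5.73 kb in TP53 KO and none elsewhere. Itk had 20.9 kb against 1.4 kb in WT and 8.45 kb in AEL, and Lck 20.9 kb against 4.4 and 16.5 kb. Cd3g, Cd2, Gimap4 and Ptcra had none in WT and 2.86, 4.8, 5.8 and 1.54 kb in TP53 KO, but also 2.63 kb (Cd3g) and 1.14 kb (Ptcra) in AEL and 1.8 kb (Cd2) and 4.82 kb (Gimap4) in BAP1 KO. Of 23 B lineage genes, 21 had H3K4me3 in TP53 KO against 17 in WT (percentile 99.4), with Blk at 7.79 kb in TP53 KO alone and Fcrla at 11.4 kb. The depletion cocktail targeted CD3e and B220. Their percentiles at equal covered length were 55.8 and 33.2, with 5.14% of the TP53 KO islands kept.

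Combined loss was compared with each single loss. H2AK119Ub was present in both Double KO animals and in no other at 1098 genes, the largest of the 10 pairs of animals (next 353), and absent from both at 6. Both libraries also held the most H2AK119Ub island reads (6765994 and 9224491, next 5566796 in TP53 KO). Combined loss and read number therefore cannot be told apart here. Of the 1098, 88.5% had H3K4me3 in WT and 8.47% H3K27me3. Vamp8 (6.05 and 3.87 kb in AML and AEL), Itih4 (7.8 and 11 kb), Mustn1 (4.35 kb in both), Ddost (9.88 and 4.28 kb) and Prr22 led the gains. Lists contributed the transferrin receptor gene Tfrc (1.91 and 4.3 kb), Cd3d, Vpreb1, Pf4, Rpl23, Rpl27, Rplp2, Rb1, Asxl2 and Ei24. Gypc, Ltf and Itk gained it at their ends but had it inside the gene in the single knockouts too, Itk over 10.2 kb in TP53 KO and 12.8 kb in BAP1 KO against 6.05 kb in AML. The losses included Inmt (6.36 kb in WT, none in AML or AEL). Fam71f2, Upb1 and the X-linked Hdac8 and Atg4a lost it at their ends only, Fam71f2 keeping 3.4 kb in AML, Hdac8 10 kb in AEL and Atg4a 11.4 and 16.4 kb against 4.59 kb in WT. H3K27me3 was gained at 44 genes, among them Frat1, Ift88, Saraf, Foxj2 and the Polycomb gene Kdm2b (12.3 and 11.1 kb against 5.4 kb in WT), and lost at 95, of which 56 (58.9%) were X-linked, against 7.12% of the 5630 genes with it in the other 3 animals. Scml1, Rhox3e, Grpr, Ppef1 and Fam122b led these losses. Ppef1 had 67.7, 118 and 68.0 kb in WT, TP53 KO and BAP1 KO, none in AML and 14.6 kb in AEL, and Fam122b kept 8.4 kb in AEL. At equal covered length H2AK119Ub gains were 83 and losses 242, and H3K27me3 losses 12. With the upper 50% of islands H2AK119Ub losses were 15 and H3K27me3 gains 23. Without Double KO AML or AEL, H2AK119Ub gains were 1750 or 3051 and losses 87 or 133, and H3K27me3 gains 484 or 205 and losses 115 or 1533.

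H3K4me3 was lost in both Double KO animals at 18 genes and gained in both at 25. The losses included the adult beta-globin gene Hbb-bs (2.6, 3.28 and 2.0 kb in WT, TP53 KO and BAP1 KO, none in AML or AEL), Gimap5, Slamf1, Kmo and Ly6d. The neighbouring beta-globin gene Hbb-bt had none in AML but 2.48 kb in AEL, so AEL did not lose H3K4me3 across this locus. Exchange of reads between these beta-globin genes was not checked in this mixed strain, so the loss at Hbb-bs is uncertain. The erythroid carbonic anhydrase gene Car1, Vwf and Ccnl1 lost it at their ends but kept 1.4, 4.6 and 9.0 kb in AEL. Gains included developmental genes Prox1 (2.4 and 3.2 kb), Six2 (1.85 and 2.85 kb), with Ccl21b and the X-linked Hs6st2, and at their ends only Foxa1 and Zfp462 (1.6 and 3.0 kb in WT). B lineage genes had H3K4me3 at 14 of 23 in AML and 13 in AEL against 17 in WT, at percentiles 1.04 and 0 of random lists. Pou2af1 had none in either. Pax5, Ebf1 and Cd22 had 11.5, 5.5 and 2.6 kb in AML and none in AEL, while Blnk and Fcer2a had none in AML and 1.6 and 4.32 kb in AEL. These percentiles were 81.1 and 27.9 at equal covered length, and 75.6 in AML with 50% of a window required. With covered length made equal, 3 genes lost H3K4me3 and 73 gained it, with the upper 50% of islands 2 and 2, and with 50% of a window required 35 lost it. Without Double KO AML or AEL the H3K4me3 losses were 31 or 505 and the gains 102 or 309.

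The 2 Double KO animals, with AML and AEL, differed from each other. H3K4me3 was present at 492 genes in AML only and 1266 in AEL only, H3K27me3 at 256 and 3326, and H2AK119Ub at 2837 and 1440. Of 39 erythroid genes, 30 had H3K4me3 in AML and 35 in AEL, against 36 in WT (percentiles 0.25 and 4.5). The AML percentile was 3.33 with a 2 kb window, 76.8 at equal covered length and 99.5 among unmatched random lists. Alas2, the erythroid heme synthesis gene, had 2.2 kb in WT, none in AML and 2.4 kb in AEL, and Epb42 and Hbb-bt also had none in AML and 3.8 and 2.48 kb in AEL. H3K27me3 was at 7 erythroid genes in AML and 18 in AEL, against 15 in WT, with Slc4a1 at 18.5 kb and Gfi1b at 9.58 kb in AEL and none in AML. Megakaryocyte genes had H3K4me3 at 5 of 19 in AML and 11 in AEL, against 8 in WT (AML percentile 0.045, and 23.9 with a 2 kb window). Gp1ba, Selp, Gp9 and Mpl had none in AML and 6.88, 10.2, 5.2 and 2.6 kb in AEL. H3K27me3 was at 10 megakaryocyte genes in AEL and 9 in BAP1 KO, against 4 in WT, 5 in TP53 KO and 3 in AML, with Pf4, Ppbp, Gp9 and, at its ends only, Gp6 in BAP1 KO and AEL (percentiles 99.4 and 99.5, and 37.4 and 42.4 at equal covered length). In AML, 27 of 60 developmental transcription factor genes had H3K4me3, against 12 in WT and 18 in AEL (AML percentile 100, and 12.2 with the upper 50% of islands). Tbx3, Foxd3 and Barhl2 had it in AML alone (2.4, 2.0 and 1.37 kb). The AML animal was also the only one set against input 2, so disease, animal and input cannot be separated, and at equal covered length H3K4me3 was present at 9382 genes in AML only and 232 in AEL only, H3K27me3 at 2196 and 428, and H2AK119Ub in AEL only at 787. With the upper 50% of islands H3K4me3 was present at 24 genes in AML only and 4101 in AEL only, and H3K27me3 at 138 in AML only.

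Stem and progenitor cell genes had more H3K4me3 in all knockout animals than in WT. 24 of 35 had it in WT, 31 in TP53 KO, 32 in BAP1 KO, 28 in Double KO AML and 30 in Double KO AEL, each above percentile 99. Cd34, Procr and Fgd5 had none in WT and 3.4, 1.4 and 2.8 kb in BAP1 KO. Flt3, a cytokine receptor gene, had 0.6 kb in WT, 11.5 kb in TP53 KO and 7.09 kb in BAP1 KO. HOX genes had H3K4me3 at 11 of 39 in WT, 23 in TP53 KO, 20 in BAP1 KO, 16 in AML and 18 in AEL (percentiles 99.9 in TP53 KO and 99.2 in BAP1 KO, and 22.1 and 14.8 with the upper 50% of islands). The Hoxa cluster (chromosome 6, 52155367 to 52260880) was covered by H3K4me3 over 21.2% in WT, 45.0% in TP53 KO, 42.5% in BAP1 KO, 18.8% in AML and 31.7% in AEL. Hoxc and Hoxd were covered by H3K27me3 over their full length in all 5 animals. Hoxb (chromosome 11, 96194316 to 96368254) was covered by H2AK119Ub over 63.6%, 81.8%, 77.2%, 48.9% and 77%, in the order WT, TP53 KO, BAP1 KO, AML and AEL. H3K27me3 was found at all 60 developmental transcription factor genes in every animal. Stem and progenitor percentiles at equal covered length were 97.6 in TP53 KO, 93.5 in BAP1 KO, 100 in AML and 41.9 in AEL, and the AML percentile was 14.6 with 50% of a window required.

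Double KO AML had H2AK119Ub at 60.6% of all genes, the highest share of the 5 animals. Polycomb and BAP1 complex genes had it at 40 of 42 in AML, against 22 in WT, 27 in TP53 KO, 28 in BAP1 KO and 30 in AEL. p53 targets had it at 28 of 31 in AML and 25 in AEL, against 14 in WT, 20 in TP53 KO and 21 in BAP1 KO. Leukemia and lymphoma genes had it at 28 of 30 in AML, against 20 in WT, 24 in TP53 KO, 25 in BAP1 KO and 25 in AEL, with Cdk6 at none in WT, 4.4 kb in TP53 KO, 12.6 kb in BAP1 KO, 16 kb in AML and 22.2 kb in AEL, and Mcl1 in AML alone. B lineage genes had it at 9 of 23 in WT, 14 in TP53 KO, 16 in BAP1 KO, 17 in AML and 16 in AEL. Mast cell and basophil genes had it at 3 of 16 in WT and 10 in AEL, stromal and endothelial genes at 9 of 22 and 14, and granulocyte and monocyte genes at 16 of 36 and 22, all within the random range (AEL percentiles 91.0, 64.1 and 39.8). Of 168 percentiles over all lists, marks and knockout animals, 33 lay above and 9 below the central 95% of random lists, where randomly drawn lists would give 8.4 in all. Of these 42, only 12 stayed outside it on the same side at equal covered length and 21 with the upper 50% of islands. Random lists were not matched on the other marks. H3K4me3 was at 38 of 38 ribosomal protein and 40 of 42 Polycomb list genes in WT, against 54.2% of all genes. It was at 87.5% of the genes that gained H2AK119Ub in the BAP1 pattern. High H2AK119Ub percentiles of such lists may therefore reflect their H3K4me3, and 8.4 is no chance level for them. At equal covered length the ribosomal protein percentile in BAP1 KO was 3.03 and in AML 82.4, p53 targets in AML stood at 31.1, and the Polycomb list in AML at 98.4.

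**Figure D3:**
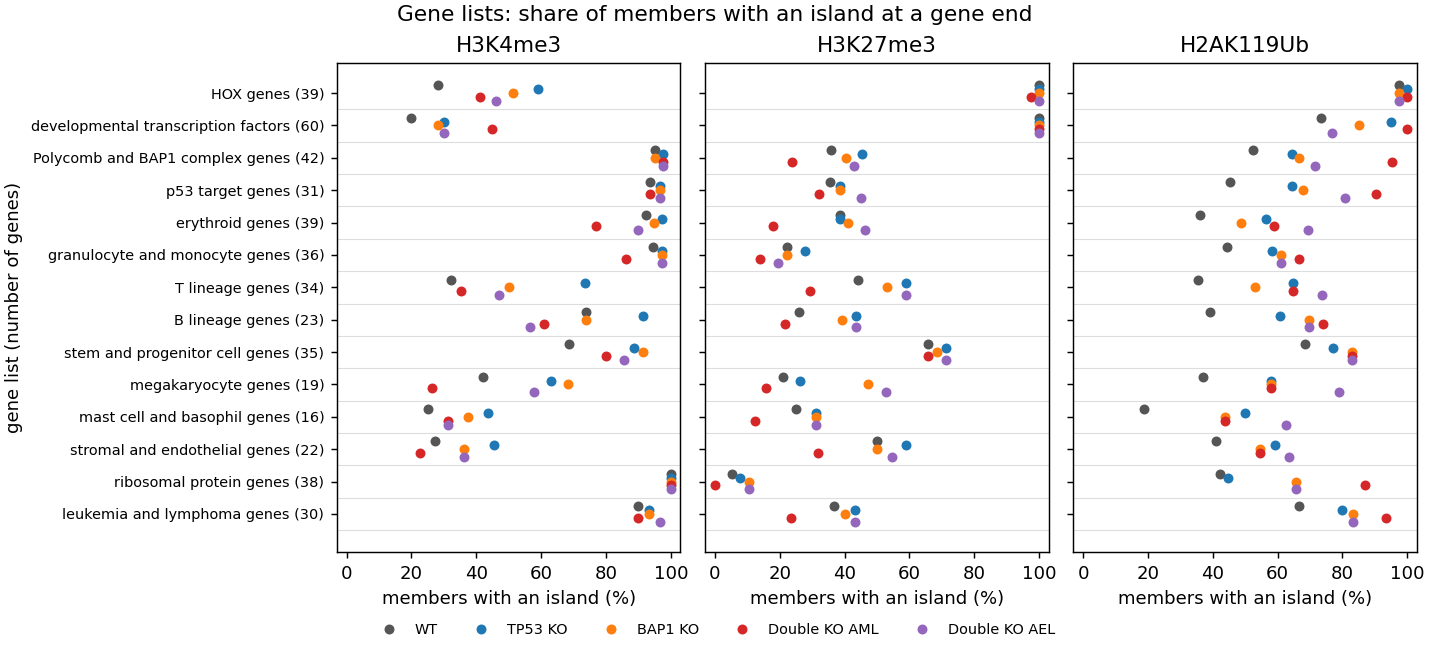
Points show the percentage of members of each of the 14 gene lists (number of genes in parentheses) that had an island at a gene end, for 3 marks and 5 animals. H3K4me3 was at 25 of 34 T lineage genes in TP53 KO, and H2AK119Ub was at 33 of 38 ribosomal protein genes in Double KO AML and 16 in WT.

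Co-occurrence asked how often the Polycomb marks shared genes in the same animal. H2AK119Ub was present at 54.3% of H3K27me3 genes in WT, 68.9% in TP53 KO, 65.8% in BAP1 KO, 85.8% in Double KO AML and 70.2% in Double KO AEL, which was 1.79, 1.53, 1.499, 1.42 and 1.295 times the share expected if marks were independent over genes. H3K4me3 genes also had H3K27me3 in 24.3%, 35.8%, 33.5%, 25.0% and 35.3% of cases, between 0.907 and 1.18 times the expected share. By length these marks overlapped more than shifted islands did. H3K27me3 covered 12.08%, 16.12%, 15.07%, 18.47% and 14.68% of H3K4me3 islands, in the same order of animals. Shifted islands gave 4.211%, 8.999%, 6.852%, 2.804% and 7.735%. H3K4me3 genes had H2AK119Ub in 44.2%, 61.0%, 60.6%, 86.7% and 75.0% of cases. In bp, H2AK119Ub covered 33.2% of H3K4me3 islands in WT, 40.9% in TP53 KO, 46.5% in BAP1 KO, 77.01% in AML and 60.55% in AEL, where shifted islands gave 3.79%, 8.60%, 8.37%, 7.55% and 13.7%. Conversely, 34.0% of the H2AK119Ub length lay in H3K27me3 islands in WT, 39.8% in TP53 KO, 31.7% in BAP1 KO, 13.8% in AML and 25.7% in AEL. Genes with H3K4me3 and H2AK119Ub but no H3K27me3 numbered 3086 in WT, 4147 in TP53 KO, 4408 in BAP1 KO, 7792 in AML and 5870 in AEL. At equal covered length the share of H3K27me3 genes with H2AK119Ub was 37.0% in AML and 38.7% in AEL, below BAP1 KO at 53.5%. H3K4me3 genes with H3K27me3 were then 7.5% in WT, 4.63% in TP53 KO, 5.95% in BAP1 KO, 25.0% in AML and 7.41% in AEL, and 11.9%, 26.0%, 22.6%, 12.4% and 25.0% with the upper 50% of islands.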

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

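The test of gene counts against island reads was chosen after the result was seen, and the test at equal covered length before. Removing 1 gene alone was compared with removing it on top of the other, as the log2 ratio or difference of BAP1 KO to WT against both Double KO animals to TP53 KO, and likewise for Tp53. A result is listed where both Double KO animals moved opposite to the single knockout. None of these differences was tested. 9 of 30 effects met this, where 25% would if all signs were random and independent. Both Double KO animals were compared with the same single-knockout library, so their signs are not independent. The 30 effects are not independent of each other either, so 25% is no chance level here.

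Loss of Bap1 alone went with more H3K4me3 genes (log2 0.16) and, on top of Tp53 loss, with fewer in AML (-0.13) and AEL (-0.04), a difference of -0.25. Because the contrast is symmetric, the same -0.246 held for Tp53. H3K27me3 genes moved by 0.31 alone and by -0.77 and -0.04 on top, a difference of -0.71. H3K27me3 islands differed by -1.41 and covered length by -1.78, and H3K4me3 covered length by -2.06, all on the log2 scale for Bap1. The share of H3K4me3 genes with H3K27me3 was 9.17 points higher with Bap1 loss alone. With Bap1 loss on top of Tp53 loss it was lower in AML and AEL (-10.8 and -0.5 points), a difference of -14.8 points.

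These lower counts in Double KO animals may come from the number of reads in islands. For H3K4me3 and for H3K27me3, marked genes ranked the 5 libraries exactly as their island reads did (rank correlation of 1 in both). Reads in islands themselves grow with the number of islands called, and WT and Double KO AML had 2556953 and 2545589 H3K27me3 island reads but 5871 and 4635 marked genes, so reads need not be the whole cause. At equal covered length the H3K27me3 difference was 1.37 in place of -0.71 (a ratio of -1.93), and 0.437 when ranked by reads per kb. The H3K4me3 difference was 1.84 by reads and 1.49 by reads per kb, in place of -0.246. These values decide nothing, because ranking by reads kept all AML islands and 5.10% of the H3K27me3 islands of TP53 KO (5.14% for H3K4me3). An interaction of Bap1 and Tp53 loss stays open.

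For the X chromosome, Tp53 loss alone went with a higher share of H3K27me3 island reads (3.02 points) and, on top of Bap1 loss, with a lower one (-7.69 points in AML, -5.19 in AEL), a difference of -9.46 points. For H2AK119Ub the values were 0.558, -0.036 and -0.449 points, a difference of -0.8 points. At equal covered length, H3K27me3 kept its directions when ranked by reads. Ranked by reads per kb, it was 5.71% in WT and 1.54% in TP53 KO, and 1.42% in BAP1 KO, 3.44% in AML and 0.905% in AEL. For H2AK119Ub, TP53 KO (2.27% by reads, 2.21% by reads per kb) stood below WT (2.91%), so the opposite movement was lost. That setting kept all WT islands of H2AK119Ub.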

How the results depend on the processing

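The added settings (gene span, gene counts without X and Y, 10 kb bins, equal covered length by reads per kb, the H3K4me3-rich gene end, and co-occurrence without WT) were chosen after the result was seen; all others were fixed before the data were examined. A log2 ratio is given below where it turned its sign or moved by more than the SD of the 2 Double KO libraries, a co-occurrence share where it moved by more than that SD, and a count where it moved by more than 1.5 times. The planned setting with any transcript start was not run, because the gene table has no transcript starts. No paired analysis was possible because the results come from no test and only the Double KO group has a second library. Except where a cause follows from how a setting is built, the cause was not tested.

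Without the X and Y chromosomes, H3K27me3 losses were 43 for the BAP1 pattern (73 before), 39 for the Double KO pattern (95) and 116 for Double KO against WT (202), and H2AK119Ub losses 6 for the BAP1 pattern (13) and 3 for the Double KO pattern (6), because those genes lie on X or Y. The log2 ratios and co-occurrence without X and Y kept to the limits above, and lists were not run. Using the gene end with H3K4me3 in more animals, and leaving WT out of the co-occurrence means moved no log2 ratio and no mean, the only results they were run on. A 2 kb window moved H3K27me3 losses of the TP53 pattern from 6 to 11 and H3K4me3 list counts below the central range from 5 to 2; the cause was not tested. Counting islands over the whole gene span moved H3K4me3 losses of the TP53 pattern from 2 to 1 and H2AK119Ub losses of the BAP1 pattern from 13 to 8 and of the Double KO pattern from 6 to 3.

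Asking that islands cover at least 50% of a window moved small counts, and the cause was not tested. H3K4me3 losses against WT were 11 in TP53 KO (19 before), 28 in BAP1 KO (18) and 49 in Double KO (30). H3K4me3 gains of the BAP1 pattern were 15 (27), its losses 9 (5), and losses of the Double KO pattern 35 (18). H3K27me3 losses of the TP53 pattern were 12 (6). H2AK119Ub losses were 9 for the TP53 pattern (4) and 14 for the Double KO pattern (6). H3K4me3 genes with H3K27me3 in AEL were 27.9% (35.3%).

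Keeping the upper 50% of islands by reads removed weak islands in every library. The log2 ratios were 0.418 for H3K4me3 in TP53 KO, 0.343 in BAP1 KO and 0.706 for H2AK119Ub in TP53 KO. Against WT, H3K4me3 gains and losses were 3088 and 2 in TP53 KO, 2470 and 8 in BAP1 KO, and 368 and 6 in Double KO, H3K27me3 gains in Double KO 159, and H2AK119Ub losses in Double KO 81. H3K4me3 pattern gains were 2 (BAP1), 5 (TP53) and 2 (Double KO), and losses 0 (TP53) and 2 (Double KO). H3K27me3 gains were 13 (TP53) and 23 (Double KO). H2AK119Ub losses were 23 (BAP1), 8 (TP53) and 15 (Double KO). Genes in AML only were 24 for H3K4me3 and 138 for H3K27me3, and in AEL only 4101 for H3K4me3. H3K4me3 genes with H3K27me3 were 11.9%, 26.0%, 22.6%, 12.4% and 25.0% in WT, TP53 KO, BAP1 KO, AML and AEL, on average 19.6%, and H3K27me3 genes with H2AK119Ub in AML 73.1%. List counts beyond the central range were 3 above and 1 below for H3K27me3 and 1 below for H2AK119Ub. The cause of each move was not tested.

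Equal covered length by reads turned the log2 ratios of TP53 KO and BAP1 KO and the Double KO means. They were -1.24, -0.751 and -0.156 for H3K4me3 in TP53 KO, BAP1 KO and Double KO, -1.08, -0.391 and -0.098 for H3K27me3, and -0.527, -0.56 and -0.614 for H2AK119Ub. The Double KO means hide opposite animals for H3K4me3 (0.807 in AML and -1.12 in AEL) and H3K27me3 (0.249 and -0.444). For H2AK119Ub both were negative (-0.284 and -0.944). The library with the least covered length, AML for H3K4me3 and H3K27me3 and WT for H2AK119Ub, keeps all its islands by construction, while TP53 KO kept 5.14%, 5.10% and 18.5%. Against WT, H3K4me3 gains and losses were 564 and 4657 in TP53 KO, 347 and 3228 in BAP1 KO, and 335 and 80 in Double KO. For H3K27me3 they were 330 and 2386 in TP53 KO and 315 and 1242 in BAP1 KO, with 111 gains in Double KO. For H2AK119Ub they were 718 and 2752, 718 and 2857, and 334 and 2125. Pattern gains and losses for H3K4me3 were 102 and 25 (TP53), 73 and 3 (Double KO) and 0 losses (BAP1). For H3K27me3, losses were 43 (BAP1) and 12 (Double KO), with 6 gains and 24 losses for TP53. For H2AK119Ub they were 58 and 243 (BAP1), 48 and 173 (TP53), and 83 and 242 (Double KO). Genes in AML only were 9382 (H3K4me3) and 2196 (H3K27me3), and in AEL only 232, 428 and 787 (H2AK119Ub). H3K4me3 genes with H3K27me3 were 7.5% in WT, 4.63% in TP53 KO, 5.95% in BAP1 KO and 7.41% in AEL, on average 10.1%. H3K27me3 genes with H2AK119Ub were 53.5% in BAP1 KO, 37.0% in AML and 38.7% in AEL, on average 51.1%. List counts were 1 below for H3K4me3, 8 above and 1 below for H3K27me3, and 6 above and 1 below for H2AK119Ub.

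Ranking by reads per kb gave log2 ratios of -1.023, -0.58 and -0.11 for H3K4me3, -0.386, -0.198 and -0.147 for H3K27me3, and -0.162, -0.194 and 0.103 for H2AK119Ub, so only the Double KO mean of H2AK119Ub kept its sign, from 0.713 in AML and -0.507 in AEL. Counting 10 kb bins gave 0.70 and 0.514 for H3K4me3 in TP53 KO and BAP1 KO, -0.075 for H3K27me3 in Double KO, and 1.018, 0.881 and 1.214 for H2AK119Ub; the cause was not tested. Random lists not matched on WT gave 29 H3K4me3 list counts above and 10 below (11 and 5 before), 16 H3K27me3 above (5) and 31 H2AK119Ub above (17), because the lists differ from all genes in WT already.

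Leaving out a Double KO library raises pattern counts by construction, since fewer libraries have to share a state. Ranges are given without AEL and without AML. For H3K4me3, Double KO gains against WT were 1093 and 1383 and losses ranged from 44 to 528. BAP1 pattern gains were 50 and 60, with losses from 6 to 9. TP53 pattern gains were 105 and 202, with losses from 2 to 8. Double KO pattern gains were 309 and 102 and losses 505 and 31. For H3K27me3, the Double KO log2 ratio was -0.341 and 0.392, with gains of 488 and 2075 and losses from 241 to 1724. BAP1 pattern gains were 49 and 225 and losses 117 and 79, TP53 gains ranged from 60 to 369 and losses from 11 to 34, and Double KO gains were 205 and 484 and losses 1533 and 115. For H2AK119Ub, Double KO gains were 6872 and 5435 and losses ranged from 225 to 265. BAP1 pattern losses ranged from 44 to 55, TP53 gains were 904 and 703 with losses from 24 to 35, and Double KO gains were 3051 and 1750 with losses from 87 to 133. List counts ranged from 1 to 4 below for H3K4me3, and from 2 to 4 above and 2 to 3 below for H3K27me3.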

Other observations

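The patterns themselves were chosen after their values were seen. Among the tests below, the tests of depth and of sex for the X chromosome share were chosen after the result was seen, and the X shares at equal covered length were added later; all other tests were planned before their results were seen.

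Regions that carried H3K4me3 in all 5 animals numbered 12732 and spanned 33.3 Mb. H2AK119Ub islands covered 39.4% of this length in WT, 50.1% in TP53 KO, 53.3% in BAP1 KO, 75.7% in Double KO AML and 62.0% in Double KO AEL. Regions with H3K27me3 in all 5 animals (6812, 48.6 Mb) showed another order, with 41.6%, 62.2%, 56.2%, 45.0% and 61.3%. H2AK119Ub was thus most extensive at shared H3K4me3 regions in the animals without Bap1, and at shared H3K27me3 regions in TP53 KO and Double KO AEL.

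The higher coverage of shared H3K4me3 regions may come from library depth, which cannot be told apart here. At equal covered length, 0 of the 3 Bap1-null libraries stood above both WT (39.4%) and TP53 KO (25.2%), with 26.6%, 37.1% and 20%, but that setting kept all WT islands and 7.84% of those of AEL, and ranked by reads per kb AML (67.2%) stood above both WT (39.4%) and TP53 KO (32.3%). The other input of the AML animal is not needed for the order, since BAP1 KO and AEL stood at least 3.20 points above TP53 KO, but the Double KO values themselves had an SD of 9.69 points, so the input cannot be told apart from no effect with these animals. Accessible chromatin recovered in every immunoprecipitate would raise H3K27me3 at the same regions, yet its highest coverage in a Bap1-null animal was below TP53 KO (-2.12 points, SD of the Double KO values 4.77), a gap too small to decide. A spread of H2AK119Ub into active promoters without BAP1 therefore remains a hypothesis that these files do not separate from depth.

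The lower X chromosome share of H3K27me3 in Bap1-null animals was weighed further. Depth stays open: WT and Double KO AML had 2556953 and 2545589 island reads and an X share ratio of 0.215, but their smallest islands held 19 and 43 reads, so equal island reads do not show equal depth. Weak islands falling below the threshold were expected to be dropped alike on X and on autosomes of like read density. Yet WT islands on X were kept over 54.8%, 6.34% and 31.7% of their length in BAP1 KO, AML and AEL, at most 0.811 times the lowest autosome. TP53 KO kept 91.0% on X, above its highest autosome (90.6%), so X and autosomes were not kept alike there either. Islands were matched on read density and not on width or read number, so a threshold effect is not excluded. Sex does not separate the animals, as 5 of 5 had an H3K4me3 island at Xist and none had an island at Ddx3y, Kdm5d, Uty or Eif2s3y. H3K4me3 at Xist relative to other X-linked genes was 0.932 or more of the lower of WT and TP53 KO in BAP1 KO and AEL, which argues against loss of the inactive X or of Xist from most cells there. It was 0.359 in AML, where that loss may account for the pattern. However, the Xist island held 53.95 reads per kb in AML and 46.62 in WT. The median at the compared X-linked genes was 128.3 in AML and 40.0 in WT. The low AML ratio therefore does not by itself show a loss.

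What stays open is why the X chromosome held a lower share of both Polycomb marks in BAP1 KO and AEL. The Xist values there, at 0.932 or more, argue against a lost X chromosome in most cells, and depth is not excluded. H2AK119Ub was lower on X as a share of reads but not in length against WT. The same held for H3K27me3 in BAP1 KO (29.7 Mb on X against 27.9 Mb in WT), but not in AML (3.94 Mb) or AEL (16.5 Mb). The pattern rests on 1 animal per disease, and age, clone size and parental strain on X were not given. Ranking islands by reads per kb at equal covered length gave H3K27me3 X shares of 5.71%, 1.54%, 1.42%, 3.44% and 0.905% in the order WT, TP53 KO, BAP1 KO, AML and AEL, which does not keep the separation, whereas ranking by reads gave 9.02%, 17.7%, 4.84%, 3.44% and 2.21%, which does. H2AK119Ub kept it under both, with 2.91% and 2.27% against 0.872%, 0.452% and 0.453% by reads. Both rankings kept all WT islands of H2AK119Ub. Of the AEL islands they kept 7.84% by reads and 16.1% by reads per kb, so this separation decides nothing.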
